A study of Patiria miniata with 6 samples.

How the data were processed

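RNA was taken from pooled bat star (Patiria miniata) embryos, and TruSeq libraries were read on an Illumina sequencer, per the labels' protocols. Zygotes had been injected with 600 µM of a morpholino antisense oligonucleotide (MASO) against Pm-Tbr, or of a standard control MASO, and cultured in seawater at 15 °C to hatching. Every control MASO sample was 30 hours post fertilization (hpf) and every Pm-Tbr MASO sample 36 hpf, so age and morpholino cannot be told apart in any comparison. Each group held 3 samples, and nothing in the labels says whether they came from separate spawnings, so p-values measure the spread between these samples, which may be technical.

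The authors deposited whole-number read counts per locus, 1 file per sample, each with 80165 loci and 5 summary lines. Per the submitters' processing notes the tools included CASAVA 1.8, TopHat2 2.0.12, SAMtools, Cufflinks 2.2.1, HTSeq 0.6.1p1 and edgeR 3.10.5. The genome build and the strand setting of the counting are not given in the sources used here. The authors also deposited a table of their own comparison with log2 fold changes, log2 CPM, a quasi-likelihood F score, p-values and false discovery rates for 27630 loci. Exactly 27630 loci had a CPM above 2 in at least 3 libraries, and all 27630 rows of the authors' deposited table were among them. Gene names and scaffold positions were taken from that table, where 12491 loci carried a name other than an uncharacterized one; loci outside it have no name here. The reference gene table was not used because it shares no identifier with the files. Several loci can carry 1 name, and reads of near-identical copies or of overlapping loci on opposite strands may be split between loci, so values are given per locus and families such as histones are uncertain.

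The summary lines stayed out of library sizes and tests. They held 49.0% to 50.6% of all lines per library, mostly reads aligned to several places (43.4% to 45.2%). Counts assigned to loci were 25423004 to 26958581 per control MASO library and 17795136 to 28167566 per Pm-Tbr MASO library. Any 2 libraries of a group differed far beyond sampling noise (chi-square per degree of freedom 38.7 to 54.6), so none was treated as a repeat of another.

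Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, after TMM scaling, with group as the only term. The filterByExpr rule left 44120 loci, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The standard error given with a log2 fold change is its size divided by the square root of F. CPM values used TMM-scaled library sizes and are given as mean ± SD over 3 libraries. Gene lists were tested with camera in limma 3.58.1 on log2 CPM, with a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry; p-values were adjusted over the 18 lists. A locus belonged to a list only if all its names did. The groups, tests, lists and most alternatives were set before the data were examined; the others were chosen after seeing the data. Names were matched to the lists afterwards without fold changes, except that a name first matched as a collagen was removed after a first look at the list tests because it is not one.

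Genes were named by a rule: up to 4 loci with the smallest adjusted p in each list, and the 10 largest rises and falls with a gene name among called loci with a mean log2 CPM of at least 1 and no overlap between groups. Pm-Tbr itself was also part of the rule, and its transcript was not analysed here.

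Samples carrying the same replicate number deviated together from their group means: the correlation across 44120 loci was 0.53, 0.22 and 0.56 for numbers 1, 2 and 3, against -0.47 to -0.05 for unlike numbers. The pairing thus comes from the deposited counts and not from a stated shared batch. Results with the replicate number as a block are printed where the count of calls moved by over 1.5 times.

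The test was tried on simulated counts for the 44120 loci with 200 changed loci. Without the block it recovered 0.0% of the 50 loci changed 1.5-fold, 0.0% of those changed 2-fold, 28.0% at 4-fold and 80.0% at 8-fold, with 6 false calls. The median estimated folds were 1.44, 1.92, 3.70 and 8.29. With the block, recovery was 10.0% at 4-fold and 60.0% at 8-fold, and none at 1.5-fold or 2-fold. The simulated libraries shared no effect of the replicate number and held only 200 changed loci. They therefore do not show the power of either fit on the real counts, where the block raised the calls from 1008 to 4455. In a second simulation the list test called a list of 40 loci raised 1.5-fold and 0 of 20 random lists. Its loci were drawn independently, so it does not cover lists whose loci vary together, as the ribosomal proteins did (estimated correlation 0.474). Alternatives covered DESeq2 1.42.0, the edgeR exact test, other scalings, filters and thresholds, the block and each library left out. The fits with a library left out were first run with loci filtered again; those that keep the loci of the 6-library filter were chosen after seeing the data.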

Results

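Pooled hatched blastulae of the bat star Patiria miniata were profiled by RNA sequencing after injection of zygotes with a morpholino against Pm-Tbr, a T-box transcription factor, or with a standard control morpholino. A morpholino antisense oligonucleotide (MASO) is a synthetic strand that binds an RNA; whether this one blocks translation or splicing is not given in the sources used here. Each group held 3 libraries, and the comparison asked which transcripts are sensitive to knockdown of Pm-Tbr. All control MASO samples were 30 hours post fertilization and all Pm-Tbr MASO samples 36, so each difference between groups is also one of age. Embryos had been sorted by a rhodamine tracer and by morphology, so embryos that failed this sort are not represented. Counts assigned to loci summed to 26366415, 26958581 and 25423004 in control MASO replicates 1 to 3, and to 18569543, 28167566 and 17795136 in Pm-Tbr MASO replicates 1 to 3. The Pm-Tbr transcript was not analysed here, so the labels were not checked against the target.

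Among the genes that differed in embryos injected with Pm-Tbr MASO were a Wnt ligand, a BMP antagonist and a chaperone. Pm-Wnt7, a secreted Wnt ligand on scaffold 2400 from 5435 to 22656, fell from 19.1 ± 4.61 CPM to 2.39 ± 0.396 CPM (SD, n = 3 per group), 7.98-fold lower with an SE of 0.31 on the log2 scale. Pm-Chordin, a secreted antagonist of BMP signals, fell from 183 ± 35.3 CPM to 7.14 ± 5.97 CPM at its more abundant locus. Pm-Hsp701E, a member of the Hsp70 chaperone family, rose from 8.34 ± 3.71 CPM to 71.6 ± 19.3 CPM at 1 of its loci. This locus lies on scaffold 49 from 22474 to 26082. The other loci of that name did not pass. The most abundant had 567 ± 210 CPM in controls and 627 ± 139 CPM in Pm-Tbr MASO embryos. Positions are in the authors' assembly, whose build is not given in the sources used here. In total 1008 of 44120 loci (2.28%) passed an adjusted p of 0.05 in the quasi-likelihood test of edgeR, 601 higher and 407 lower in Pm-Tbr MASO embryos. Of these, 410 carried a gene name, 194 of the higher and 216 of the lower loci, and 598 were uncharacterized or had no name. All 1008 had no overlap in CPM between groups, which was true of 26.5% of all tested loci against 10% by chance. The 10% holds for interchangeable libraries, whereas same-numbered libraries deviated together. With the replicate number as a block the count was 4455, 2574 higher and 1881 lower, and it included all 1008. The smallest adjusted p was 0.0190, and leaving out control MASO replicate 1 or 2 and filtering the loci again left 0 calls in this test without the block, against 8561 and 6886 loci at an unadjusted p under 0.05 and 2710 and 1619 calls by the edgeR exact test. With the loci of the 6-library filter kept, 209 calls were left without control MASO replicate 1, and still 0 without control MASO replicate 2, where 6643 loci had an unadjusted p under 0.05. The balance of directions also moved; with the loci filtered again, 50 loci were higher and 50 lower without control MASO replicate 3, and 12 and 1, 104 and 14, and 298 and 120 without Pm-Tbr MASO replicates 1, 2 and 3.

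**Figure D1:**
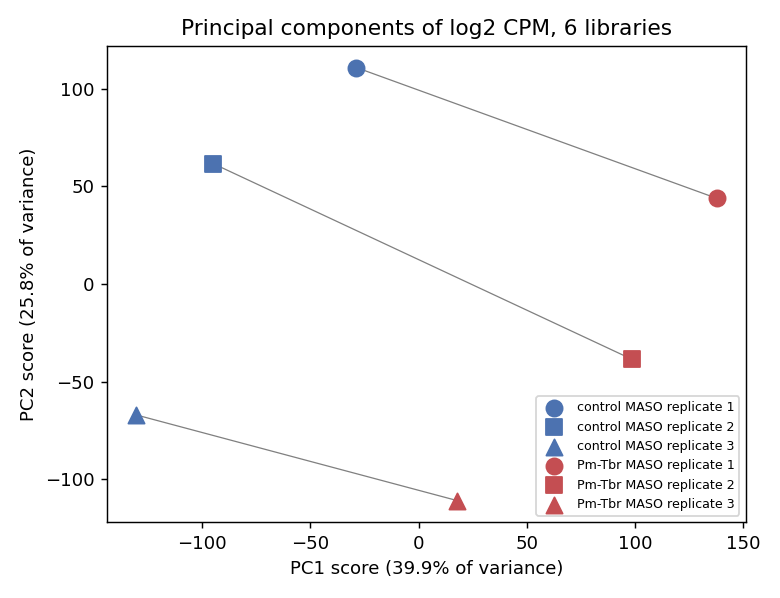
Principal components of log2 CPM over 44120 loci, with scores on both axes, colour for the group, marker shape for the replicate number and a line joining same-numbered libraries. The first component held 39.9% of the variance and the second 25.8%; in each pair the Pm-Tbr MASO library lies to the right of and below its control.

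Of 22 loci of endoderm and endomesoderm regulators, 4 fell, 0 rose and 18 did not pass. Pm-Eve, a homeobox gene, fell from 159 ± 29.4 to 50.6 ± 4.72 CPM (log2 fold change -1.65 ± 0.22 SE, adjusted p = 0.0238). Pm-Bra, the T-box gene brachyury, fell from 184 ± 21.3 to 57.8 ± 20.2 CPM (-1.67 ± 0.30, adjusted p = 0.0354), although its other locus, at -1.13, did not pass (adjusted p = 0.350). Both loci of the homeobox gene Pm-Hox11/13b, which share 1 gene model, fell by 1.26 and 1.35 on the log2 scale. The list's median was -0.67, and camera placed it below other loci (adjusted p = 0.00053; adjusted p = 0.183 with an estimated correlation). Of 37 loci of ectoderm and apical regulators, 6 fell, 0 rose and 31 did not pass. Pm-Msx fell from 9.48 ± 2.24 to 0.751 ± 0.810 CPM, Pm-Gsc (goosecoid) from 51.4 ± 13.4 to 9.80 ± 6.81 CPM and Pm-Hbn (homeobrain) from 61.9 ± 18.8 to 15.2 ± 5.71 CPM, with log2 fold changes of -3.67, -2.39 and -2.02. Pm-Nkx2.1, which lies outside the rule for named genes and was added after its value was seen, had a log2 fold change of -2.96 (adjusted p = 0.0461). Pm-Nk1 fell by 1.72 and 2.12 at 2 overlapping loci, while 3 loci of that name elsewhere had values of 1.20, 1.74 and 1.49 that did not pass without the block and were called higher with it, so its direction differs between loci. The ectoderm list had a median of -0.65 (adjusted p = 0.00063; adjusted p = 0.185 with an estimated correlation). Of 22 loci of mesoderm and mesenchyme regulators, 1 rose and 1 fell. Pm-Gcm, a transcription factor that specifies pigment cells in sea urchins, fell by 2.49 ± 0.35 on the log2 scale, and Pm-Jun, a component of AP-1, rose by 1.34 ± 0.26. That list did not pass the test against other loci (adjusted p = 0.470). Adjusted over the list alone, 7 endoderm loci fell and 2 rose, 13 ectoderm loci fell and 4 rose, and 2 mesoderm loci changed each way. With the block the counts were 7 lower and 2 higher, 12 lower and 5 higher, and 2 lower and 3 higher.

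In the Wnt list of 47 loci, Pm-Wnt7 and Pm-Dkk1, a secreted Wnt antagonist, fell and 45 loci did not pass. Pm-Dkk1 dropped by 1.51 ± 0.25 on the log2 scale (adjusted p = 0.0318). In the Nodal and BMP list of 41 loci the falls were both at Pm-Chordin, with log2 fold changes of -4.66 and -4.70, on scaffold 13369 from 6232 to 17986 and from 3970 to 6181, which share 1 gene model. No locus of the 25 in the Delta-Notch list or the 17 in the FGF, VEGF and MAPK list passed. Camera gave adjusted p = 0.522 for the Wnt list, whose median was 0.15 while its mean was -0.08 and its test pointed down, 0.305 for Nodal and BMP and 0.670 for Delta-Notch. The FGF list was placed higher (median 0.32, adjusted p = 0.0409), and this ended with the block (adjusted p = 0.0738), with an estimated correlation (adjusted p = 0.293), with 1 locus per gene name (adjusted p = 0.371) and without control MASO replicate 3, Pm-Tbr MASO replicate 1 or Pm-Tbr MASO replicate 3 (adjusted p = 0.141, 0.137 and 0.0750). Adjusted over the list alone, 2 Wnt loci fell and 3 rose, 3 Nodal and BMP loci fell and 1 rose, 4 FGF loci rose, and 0 Delta-Notch loci passed. With the block, 3 Wnt loci were lower and 6 higher, 4 Nodal and BMP loci lower and 1 higher, 4 FGF loci higher, and 3 Delta-Notch loci lower and 2 higher.

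**Figure D2:**
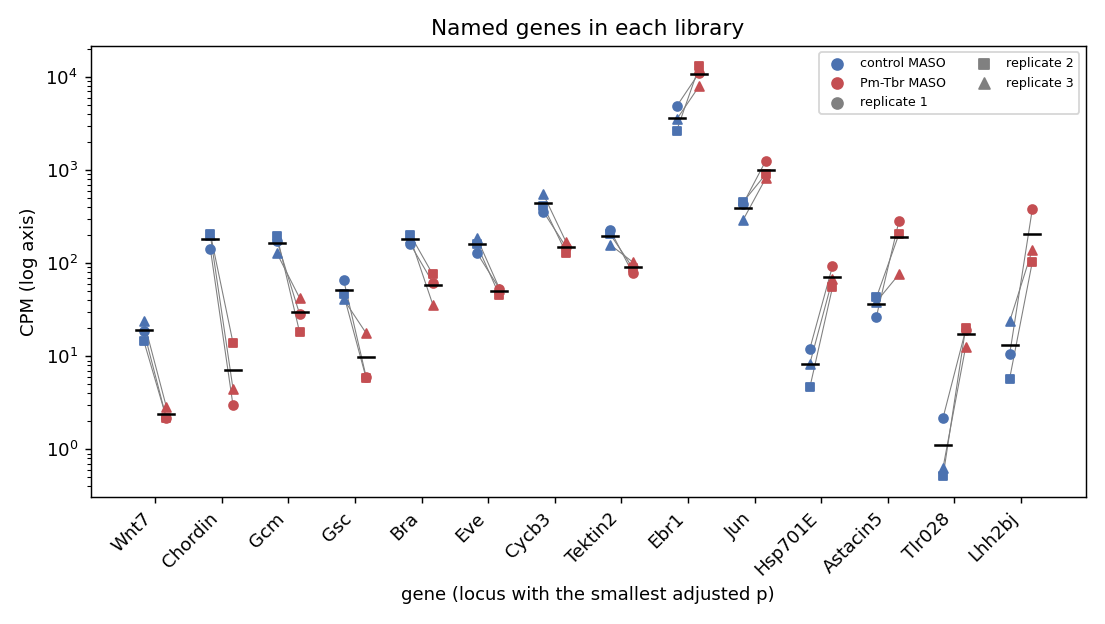
CPM on a log axis in each library for named genes at the locus with the smallest adjusted p, with blue points for control MASO, red for Pm-Tbr MASO, a shape for each replicate number, grey lines joining same-numbered libraries and a black bar at each group mean. In every gene shown the 3 libraries of a group lie on 1 side of the other 3; Pm-Ebr1 has the highest level, with means of 3665 and 10723 CPM.

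Of 165 cilia loci, 4 fell and 161 did not pass, where 2.28% of all 44120 tested loci were called. Among the 12491 named loci 410 were called. The counts of calls for cilia, cell cycle and stress loci thus do not set these lists apart. The cilia falls were Pm-Ift140_1, part of the transport machinery of cilia, Pm-Ia1/Ic140-2, a dynein intermediate chain name, and the doublet proteins Pm-Tektin1-2 and Pm-Tektin2. Their log2 fold changes were -1.12, -1.13, -1.20 and -1.13, and Pm-Tektin2 fell from 198 ± 36.0 to 90.4 ± 12.3 CPM, while 2 further loci named Pm-Ift140_1, at -0.19 and 0.26, did not pass. The cilia list had a median of -0.53 (adjusted p = 9.5e-07; adjusted p = 0.312 with an estimated correlation), with medians of -0.62, -0.64 and -0.18 in the pairs 1, 2 and 3. Of the cell cycle loci, 2 fell, 0 rose and the rest did not pass; the falls were both named Pm-Cycb3 (cyclin B3), with log2 fold changes of -1.56 and -1.78, at loci of 1 gene model, one lying within the other. Another locus of that name and gene model, at -0.23, did not pass. That list had a median of -0.23 (adjusted p = 0.0015; adjusted p = 0.312 with an estimated correlation). Of 93 loci for p53, apoptosis and stress, 1 locus of Pm-Hsp701E rose and 2 loci of Pm-Hsp40C, a cochaperone name, each fell by 1.51. The list did not pass (adjusted p = 0.330). Adjusted over the list alone, 18 cilia loci fell, 2 cell cycle loci fell, and 2 stress loci changed each way. With the block, 20 cilia loci were lower and 1 higher, 10 cell cycle loci lower and 2 higher, and 12 stress loci higher and 3 lower.

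Of 32 hatching and extracellular protease loci, 3 rose and 1 fell. Pm-Mt1-4/MmpL4, a matrix metalloproteinase name, had a log2 fold change of 3.18 ± 0.52, Pm-Astacin5 rose from 36.1 ± 8.39 to 190 ± 106 CPM, and Pm-Adam15L1 had a log2 fold change of 1.68 at 1 locus and -0.16, not passing, at another. The fall was at the minor locus of Pm-Mt6_mmpL, by 1.81 ± 0.29 on the log2 scale, while its far more abundant locus had 5440 ± 1770 CPM in controls and 11514 ± 6988 CPM in Pm-Tbr MASO embryos, which did not pass (log2 fold change 1.08, adjusted p = 0.257). The list's median was 0.86 (adjusted p = 0.00097; adjusted p = 0.185 with an estimated correlation). In the germline and maternal list of 36 loci, 5 rose and 1 fell. Pm-Ebr1, the egg receptor for sperm bindin, rose from 3665 ± 1108 to 10723 ± 2532 CPM, 2 loci of the yolk protein name Pm-Vtgn1 had log2 fold changes of 1.95 and 1.87 and 2 of Pm-Vtgn2, added after their values were seen, 1.62 and 1.54, and Pm-Cpeb2, a regulator of polyadenylation, fell by 1.91 ± 0.25. This list had a median of 0.32 (adjusted p = 0.0107; adjusted p = 0.312 with an estimated correlation), and the call ended with 1 locus per gene name (adjusted p = 0.158). Its medians in the pairs 1, 2 and 3 were 0.45, 0.53 and -0.08, so pair 3 went the other way. Of 96 loci marking muscle, neurons and immune cells, 7 rose and 0 fell. They included Pm-Tlr028, a Toll-like receptor name, from 1.11 ± 0.932 to 17.4 ± 4.10 CPM, and the scavenger receptors Pm-Srcr159 and Pm-Srcr28, the latter from 4.64 ± 1.25 to 18.8 ± 5.37 CPM at 1 of its 2 called loci. The uncalled loci of both names had values of either sign. Pm-Syt6-2, a synaptotagmin added after its value was seen, had a log2 fold change of 2.44. The call on this list (median 0.23, adjusted p = 0.0132) ended with an estimated correlation (adjusted p = 0.183), with 1 locus per gene name (adjusted p = 0.333) and without Pm-Tbr MASO replicate 3 (adjusted p = 0.0689). Adjusted over the list alone, 13 protease loci rose and 2 fell, 14 germline loci rose and 3 fell, and 11 marker loci rose and 2 fell. With the block these counts were 14 and 3, 12 and 2, and 13 and 4.

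Of the extracellular matrix loci, 4 rose and 141 did not pass; they were Pm-ThrombA1, Pm-Egf/HyalinL14, Pm-Sea/Egf/Hyalinl and Pm-Co5a1, with log2 fold changes of 4.57, 2.42, 2.33 and 2.09. Other loci named Pm-ThrombA1 or Pm-Sea/Egf/Hyalinl had values of either sign that did not pass without the block. The matrix list missed the threshold (adjusted p = 0.0528) and passed it without control MASO replicate 1 or Pm-Tbr MASO replicate 2 (adjusted p = 0.0381 and 0.0450) and with the loci of the authors' table (adjusted p = 0.0197). The biomineralization list was built from skeleton genes of sea urchins, while sea star larvae form no skeleton. Of its 11 loci, Pm-Cara14LA rose from 19.5 ± 4.96 to 51.2 ± 6.08 CPM. Of 17 histone loci Pm-Lhh2bj and Pm-LhH1a rose, the former from 13.3 ± 9.30 to 207 ± 150 CPM. Another locus named Pm-LhH1a had a value of -0.38. Reads of histone copies may be split between loci, and the histone list had a median of -0.14 but a mean of 0.94 with a test that pointed up (adjusted p = 0.323). The biomineralization list gave adjusted p = 0.494. None of the 93 ribosomal protein loci passed, yet 89 had negative values with a median of -0.57 (adjusted p = 1.8e-12; adjusted p = 0.323 with an estimated correlation). None of the 96 mitochondrial loci passed either, with a median of -0.30 (adjusted p = 0.00038; adjusted p = 0.312 with an estimated correlation). Adjusted over the list alone, 10 matrix, 3 biomineralization and 5 histone loci rose, 1 histone locus fell, and 0 ribosomal and 0 mitochondrial loci passed. With the block, 11 ribosomal protein loci and 10 mitochondrial loci were lower, 19 matrix loci higher and 7 lower, 2 biomineralization loci higher and 5 histone loci higher.

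**Figure D3:**
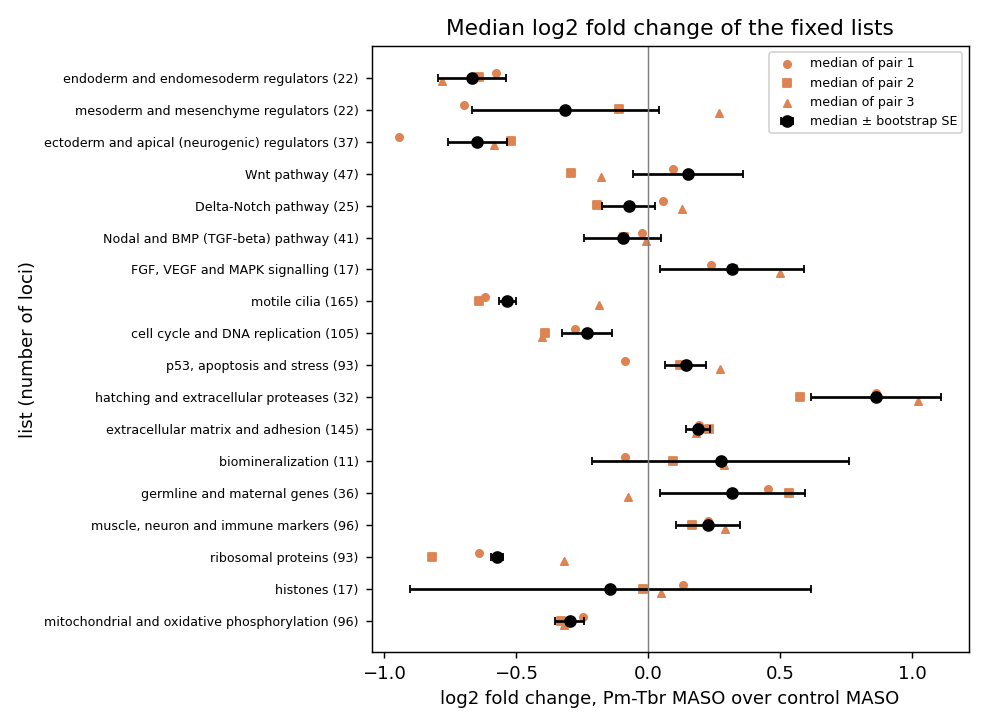
Median log2 fold change of each fixed list (horizontal axis, Pm-Tbr MASO over control MASO), with a bootstrap SE over loci as the bar, the number of loci in brackets and orange marks for the medians of the 3 same-numbered pairs. Ribosomal protein loci have a median of -0.57 and the hatching and protease list one of 0.86.

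Rises and falls were ranked among called, named loci with no overlap between groups and an edgeR average log2 CPM of at least 1. Pm-AapL had the largest fitted rise. At this locus the control libraries held 2 counts in all against 233 in the Pm-Tbr MASO libraries. After scaling by library size the ratio was 141, with a counting interval of 38.5 to 1169. Other loci named Pm-AapL, with log2 fold changes of 0.04, 0.02 and 0.02, did not pass (adjusted p = 0.956, 0.988 and 0.985). The first of these was far more abundant than the locus that rose. Pm-Helz2, a helicase name, followed with a log2 fold change of 5.75 ± 0.87, and Pm-Eif5A, a translation factor name, with 0.846 ± 0.277 against 23.7 ± 17.7 CPM. A neighbouring locus named Pm-Eif5A also rose (log2 fold change 4.75, adjusted p = 0.0389), while 3 others had values of -1.06, -1.03 and -0.83 that did not pass without the block and were called lower with it. The other large rises were Pm-Tmem26_5, Pm-ThrombA1, Pm-Pi16, Pm-Tirc5, Pm-Ache_19, Pm-Tlr028 and Pm-Lhh2bj, with log2 fold changes from 3.96 to 4.70. More abundant loci named Pm-Tmem26_5, Pm-Tirc5 and Pm-Ache_19, at 0.39, 0.71 and 0.87, did not pass (adjusted p = 0.531, 0.173 and 0.520). A further Pm-Tmem26_5 locus was called at 2.57. Below Pm-Chordin, the largest falls were Pm-HnrpcL_1 (log2 fold change -4.13 ± 0.50, with 2 further loci called at -3.90 and -1.51), the exchanger Pm-Slc24a3 (-3.80), the cytochrome P450 names Pm-Cyp3L8 (-3.73) and Pm-Cyp3L2 (-3.34), Pm-St8sia1_1 (-3.70), Pm-Msx, Pm-Amt1 (-3.65), Pm-Ugt2b17L (-3.22) and Pm-XerdL (-3.05). For some of these names other loci went the other way. Pm-Cyp3L2 had 2 loci, with means of 0.784 against 7.30 CPM and of 0.926 against 7.42 CPM, that did not pass without the block and were called higher with it (block adjusted p = 0.0159 and 0.0176), and Pm-Cyp3L8 one at 2.09 (adjusted p = 0.0955) that passed in neither fit. Pm-Slc24a3 had a locus at 0.34 and Pm-Amt1 one at 0.09, neither of which passed. This Pm-Slc24a3 locus had means of 30.2 against 38.4 CPM, while the called one had 20.4 CPM in controls. The most abundant Pm-Amt1 locus had means of 212 against 198 CPM and did not pass (log2 fold change -0.095, adjusted p = 0.938). The called Pm-Amt1 locus had only 13.5 CPM in controls. A further Pm-Amt1 locus, at -0.96, was called lower only with the block. Adjusted p for the 20 ranked genes, at the loci that were ranked, lay between 0.0190 and 0.0446.

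The authors' deposited table called 2562 loci at a false discovery rate under 0.05, 1521 higher and 1041 lower. It gave Pm-Wnt7 a log2 fold change of -2.97 and the locus of Pm-Hsp701E called here one of 3.14. Of the 1008 loci called here, 122 are outside the authors' deposited table, and the other 886 were all called there, in the same direction. These were 34.6% of the authors' calls, against 98.9% with the replicate number as a block. Across 27630 loci, which are not independent replicates, Pearson's r between the log2 fold changes was 0.994 and Spearman's rho 0.995; both come from the same libraries.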

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

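The test of sequencing depth was chosen only after the result was seen. Reads that fell outside every locus, which no comparison in the report uses, made up 2.84% ± 0.0143 of all lines in the Pm-Tbr MASO libraries and 2.31% ± 0.0254 in the control MASO libraries (SD, n = 3 each). The groups did not overlap (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allows), while the ambiguous share was lower, 2.79% against 2.90%. Depth alone is argued against, because the deepest Pm-Tbr MASO library lay 0.503 percentage points above the highest control share, when the control shares spanned 0.0507. Background reads spread evenly over the genome stay open: loci without a strand had a median log2 fold change 0.0439 ± 0.0134 (bootstrap SD) above matched stranded loci, between the bounds set for and against. Age and morpholino are open and untested.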

How the results depend on the processing

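The replicate pairs left out, the loci of the authors' table, the fits without re-filtering, DESeq2 with the block, 1 locus per gene name and library-size scaling of the lists were chosen after seeing the data. Against 1008 changed loci, DESeq2 gave 4039, the edgeR exact test 3394, the replicate block 4455 and DESeq2 with the block 6425. Against the 4455, the block gave 852 without pair 1, 5722 without pair 2 and 1601 without pair 3. These 3 fits called 512, 1007 and 708 of the 1008 loci. No locus passed an adjusted p of 0.01 in the quasi-likelihood test, in which 8832 had an unadjusted p under 0.05. With each library left out the count ranged from 0 to 479; the highest keeps the filter of all 6 libraries, under which leaving out control MASO replicate 1 gave 209 rather than 0. Without the block, other scalings, filters, a 2-fold minimum and the authors' loci gave 1002 to 1449. Of the 57 named loci, 0 to 27 stayed called with a library left out and 31 with the block without pair 1; other settings kept 49 to 57. Of 18 lists, 10 were called, 0 with an estimated correlation and 6 with fry, and 7 to 11 otherwise. The calls that ended with fry were cilia, cell cycle, ribosomal and mitochondrial (adjusted p = 0.0580, 0.0744, 0.0580 and 0.0736). The share of the authors' calls found here was 34.6%, 86.3% with the exact test and 98.9% with the block. Fewer samples underlie the left-out fits; for the other settings the cause was not tested. No named locus changed sign and no list test changed direction, but medians of 2 lists that were not called changed sign. In log2 CPM the mesoderm median of -0.33 became 0.15 without control MASO replicate 1 and 0.01 without Pm-Tbr MASO replicate 3. The Wnt median of 0.04 fell below 0 without any single library except Pm-Tbr MASO replicate 2, down to -0.21 without Pm-Tbr MASO replicate 1, and was -0.01 without a filter on low counts and -0.08 with 1 locus per gene name. The block changed 1 list call, that of FGF, VEGF and MAPK, and no named locus. The alternatives for the Pm-Tbr transcript were not run. In simulated counts at this depth, 0 of 50 loci changed 2-fold were recovered.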

Other observations

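No test in this part was chosen after its result was seen, but the gene families here were assembled after the largest changes had been looked at. Genes of innate sensing and antiviral defence held 8 rises and 0 falls among 80 loci. Pm-RigIL6, a RIG-I-like name, rose from 2.81 ± 1.78 to 39.6 ± 17.9 CPM (SD, n = 3 per group), and Pm-Ddx58_3, also named for RIG-I, from 3.24 ± 2.60 to 27.2 ± 10.7 CPM at 1 of its loci. The deubiquitinase Pm-Cyld had log2 fold changes of 1.85 and 1.66 at 2 loci. Ribosome biogenesis genes held 5 falls among 86 loci, among them Pm-Nop5 from 173 ± 17.0 to 73.7 ± 12.8 CPM, and the proteasome 3 falls among 46 loci, among them Pm-Psma7 from 79.4 ± 13.2 to 28.1 ± 4.11 CPM. The Hedgehog ligand Pm-Hh_1 fell at 3 loci, of which 2 share 1 gene model, by 2.63, 2.76 and 3.03 on the log2 scale, the only calls without the block among 19 pathway loci. Conjugation enzymes (sulfotransferases, glucuronosyltransferases and glutathione transferases) held 3 falls among 21 loci, among them Pm-Sult1b1_1 at -1.78. The sets went both ways in solute carriers (6 rises and 11 falls of 313), cytochrome P450 (2 and 3 of 74), numbered zinc fingers (3 and 5 of 132), neuropeptide and amine receptors (2 and 4 of 37) and transposon-like loci (1 and 1 of 54), and 2 of 6 late histone loci rose. With the replicate number as a block, 29 innate sensing loci were higher and 2 lower, the latter Pm-Sarmr12 and Pm-Parp16, and 18 ribosome biogenesis and 11 proteasome loci were lower with 0 higher. Blocked counts of higher and lower loci were 1 and 7 for conjugation enzymes, 1 and 3 for Hedgehog, 18 and 31 for solute carriers, 11 and 11 for cytochrome P450, 11 and 12 for zinc fingers, 5 and 6 for the receptors, 2 and 2 for transposon-like loci and 3 and 0 for late histones. Of these 11 families, 4 passed camera: innate sensing (adjusted p = 2.7e-08), ribosome biogenesis (2.3e-06), conjugation enzymes (2.7e-05) and the proteasome (0.000138). Because the families were assembled after the largest changes in the same libraries were seen, their p-values only describe them and are no independent test. None of the 4 families held with an estimated correlation (adjusted p = 0.239, 0.191, 0.239 and 0.191). With fry the adjusted p was 0.0384, 0.0164, 0.0384 and 0.0164, under the same limit. The other 7 did not pass, with adjusted p from 0.0777 for late histones to 0.9996 for cytochrome P450.

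The count of 1008 called loci was the highest of the 10 splits of the 6 libraries; the value of 1 split with as many calls includes the real one, and the highest other split gave 0 by the edgeR quasi-likelihood test, with at most 4231 loci at an unadjusted p under 0.05. For the lists, 1 split gave as many as the real 10 and the highest other gave 4. Of the splits, 4 part all 3 same-numbered pairs, and the other 3 of these gave at most 0 loci and 3 lists; the remaining 6 part 1 pair. With 10 splits no share under 0.05 can be reached. Every other split also mixes control MASO and Pm-Tbr MASO libraries on both sides. Any difference between those groups then adds to the spread within each side, so low counts there cannot decide on chance.

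Innate sensing loci had a median log2 fold change of 0.84, with 63 of 80 above 0. Without the names first noticed, the median over the 71 remaining loci was 0.83 ± 0.18 (bootstrap SD over loci). The rise was thus not confined to those names. This was no test, since with 63 of 80 loci above 0, removing 9 could not bring the median to 0. A rise confined to 1 pair of libraries is argued against, as the medians of pairs 1, 2 and 3 were 0.87, 0.85 and 0.87. The bootstrap SD over loci of the lowest, 0.21, does not measure the spread between libraries. These loci also vary together (estimated correlation 0.145). The names first noticed came from loci with no overlap between groups, which favours positive values in every pair. A candidate explanation is a response to the injected oligonucleotide or an older embryo; both groups received an oligonucleotide and the ages differ, so the design leaves these open and untested.

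Of 93 ribosomal protein loci, 89 had negative log2 fold changes, although none passed the test singly without the block. Loss of abundant transcripts in general is argued against, because other named loci matched on mean expression had a median of -0.13 ± 0.07 (bootstrap SD over loci) against -0.57. A single deviating pair is argued against too, as the medians of pairs 1, 2 and 3 were -0.64, -0.82 and -0.32. The bootstrap SD over loci of the last, 0.02, does not measure the spread between libraries. The estimated correlation between ribosomal protein loci, 0.474, is high, so they are far from independent. Age and morpholino stay open, untested.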
